A study of Mus musculus and Homo sapiens with 32 samples.

How the data were processed

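The series holds 32 arrays. RNA of 20 mouse lung tumours from 15 mice was labelled with biotin and measured on 1-channel probe set arrays, and RNA of 6 derivative human cell lines, each kept at 3% and at 21% oxygen, was measured on 12 arrays with 2 dye channels. Groups were taken from the sample labels alone.

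The deposited mouse values are log2 probe set levels made with RMA, per the submitters' processing notes. The version of RMA, the arrays normalised together and the annotation are not given in the sources used here. The 20 mouse columns had medians between 4.84 and 5.04 on the log2 scale. The deposited human files give the mean spot intensity and the local background of both channels, per the file headers, together with background-subtracted and lowess-normalised intensity values and their log2 ratio of channel 2 over channel 1. The scanner, its software and the settings of that lowess are not given in the sources used here. The deposited series matrix of the human arrays matched the spot-averaged log2 ratio of the scanner files to within 0.005, so its scale and its direction, channel 2 over channel 1, are known, and how the authors centred it is not. Its column medians at 3% and 21% oxygen were 0.04 and 0.04 for A549 LKB1-WT, 0.035 and 0.039 for A549 kinase-dead, 0.04 and 0.043 for A549 parental, 0.17 and 0.16 for the first and 0.181 and 0.185 for the second line labelled H2126 LKB1-WT, and 0.043 and 0.053 for H2126 parental. Columns of samples outside the labels numbered 0.

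The labels give no dyes and name channel 2 as the common reference. The rule for this, set with the design, was to take the channel varying less between the 12 arrays as the reference. Channel 1 varied less in 99.8% of probes, and its rank correlation between arrays was 0.990 to 0.998, against 0.630 to 0.993 for channel 2. Ratios were therefore read as channel 2, the sample, over channel 1, the reference, opposite to the label. Every sign in the cell line results rests on this reading.

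Human intensities were background-corrected with normexp (offset 50) and normalised by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0 and then left out. Files were read with the R package data.table, version 1.17.8. Each array held 45220 spots, 2542 of them control spots, and the files marked 0 spots as saturated or bad. Spots of a probe were averaged, which gave 39980 probes. A probe was kept when its sample channel lay more than 2.6 background SD above the local background on at least 2 arrays, a stand-in for a scanner's own flag, which left 38975. Of all probes 36350 carried 1 gene symbol, 254 several and 3376 none, and 2700 of the symbols came from the files' sequence match column. The probe with the highest mean signal stood for its gene, which gave 18018 genes. Symbols are those of the array's design and some are old. Mouse values were used as deposited with no filter on 22690 probe sets. Mouse probe sets were not paired with genes here, so mouse results are given for probe sets without gene names, and the mouse gene lists and the comparison of mouse genes with their human counterparts were not analysed here.

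Before the data were examined, the samples, comparisons, tests, gene lists and the alternatives of processing were fixed, apart from those named below as chosen later. Differences were tested with limma (lmFit and eBayes) on log2 values, with Benjamini-Hochberg adjustment and a threshold of 0.05. For tumours the mouse was the replicate, and tumours of 1 mouse were averaged first, which concerned 4 mice. The L/+ mouse and the metastasis stood outside both groups. For cell lines the comparison across both lines used 6 derivative lines averaged over oxygen with cell line as a covariate, and the other LKB1 comparisons used all 12 arrays with an oxygen term. The oxygen comparison used the derivative line as a block, because the labels give each derivative line at both oxygen levels, and arrays of the same derivative line correlated at 0.941 to 0.978, while A549 kinase-dead and parental arrays at 3% oxygen also correlated at 0.978. Each derivative line has 1 array per oxygen level and nothing says that cultures were independent, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. The files give no slide or scan batch, and none was tested.

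Of 15 fixed human gene lists, 13 were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 13 lists of a comparison. A call lost with the estimated correlation is not by itself a sign of correlated genes, since p also rose where the estimate lay below 0.01. They cover squamous and basal epithelium, alveolar type 2 cells, gut-like and mucinous epithelium, proliferation, hypoxia and glycolysis, p53 targets, sterol and fatty acid synthesis, CREB and CRTC targets, NRF2 targets, EMT and invasion, interferon response, ATF4 targets with the unfolded protein response, and fibroblasts with extracellular matrix. The genotype genes and the study genes NEDD9, VEGFC and CD24 were read gene by gene. The study chose the latter on these samples, so no count of them is independent evidence. The genes named are the genotype and study genes, the 5 largest increases and the 5 largest decreases among genes past the threshold whose groups did not overlap (clone names left out; the 3 with the smallest p where none passed), and up to 3 members past the threshold of each list called by camera, or the 2 with the largest moderated t where none passed. Other genes named belong to the fixed lists and were picked after their values were seen. Some genes that the rule names are not reported here.

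RNA quality of the tumours was read from the log2 difference between the 3' and 5' probe sets of Gapdh and of actin. Its group differences were tested with exact 2-sided permutation tests. The limma fits of the comparisons fixed beforehand were tried on simulated data with known changes, as was camera for A549 LKB1-WT against kinase-dead. The permutation tests were not. At a log2 change of 1 the simulation of A549 LKB1-WT against kinase-dead, over 18018 genes, recovered 56.7% of the changed genes, that of all primary tumours, over 22690 probe sets, recovered 80.6%, and that of the comparison across both cell lines, over 18018 genes, recovered 0%, also at a log2 change of 2. In the simulation of the lists 1 of 13 lists was shifted and called and 0 others were called. Its genes varied independently, while estimated correlations of the real lists reached 0.48. It therefore cannot show false calls from correlated genes.

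Alternatives covered background correction, normalisation, the filter on dim probes, the series matrix, every probe without collapse to genes, the control genotype, the block, and each mouse, derivative line or array left out. The fits without the 4 arrays labelled H2126 LKB1-WT, the A549-only fits, the Gapdh covariate and the omission of single arrays were chosen after the data were seen. The comparison of A549 LKB1-WT with parental cells by itself was not among those fixed beforehand. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.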

Results

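The experiment profiled lung tumours of K-ras mice with and without Lkb1 loss, and human lung cancer cell lines given back LKB1, a serine/threonine kinase encoded by STK11. The 20 mouse arrays covered 15 mice. Lkb1-intact adenocarcinomas came from 5 mice with p53 loss and 2 with p16 loss. Lkb1-loss primary tumours came from 2 L/L and 5 L/- mice, of which 4 carried adenocarcinomas, 2 squamous tumours and 1 mixed tumours. A metastasis of 1 L/L mouse and 2 adenocarcinomas of 1 L/+ mouse completed the set. The 12 human arrays covered A549 and H2126, established lines of human lung cancer, with 6 arrays each: A549 parental, A549 with wild-type LKB1, A549 with kinase-dead LKB1, H2126 parental and 2 lines labelled H2126 LKB1-WT, each at 3% and 21% oxygen.

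Lkb1-loss tumours (7 mice) and Lkb1-intact tumours (7 mice) differed at 5201 of 22690 probe sets, with 2428 higher and 2773 lower after Lkb1 loss (limma, adjusted p under 0.05). Of these, 605 rose and 246 fell by more than 2-fold. At matched histology, adenocarcinomas of 4 Lkb1-loss mice and 7 Lkb1-intact mice differed at 1337 probe sets, 934 higher and 403 lower. Among probe sets past the threshold without overlap between groups, that with the largest increase in Lkb1-loss adenocarcinomas rose from 4.56 ± 0.90 (SD, n = 7) to 9.21 ± 1.84 (n = 4), a log2 difference of 4.65 (SE 0.69, limma adjusted p = 0.0049). The probe set with the largest decrease fell from 9.24 ± 1.45 to 4.34 ± 0.38, a log2 difference of -4.90 (SE 0.65, limma adjusted p = 0.00325). The 3' to 5' difference of Gapdh, a sign of RNA quality, moved with the groups: it was 1.80 ± 0.37 on the log2 scale in Lkb1-intact mice (SD, n = 7) and 0.75 ± 0.80 in Lkb1-loss mice (n = 7; exact 2-sided permutation p = 0.0128, adjusted over 3 comparisons p = 0.0385). In adenocarcinomas alone the group difference was -0.74 (exact permutation p = 0.103, adjusted p = 0.155). With the Gapdh difference as a covariate 363 probe sets passed in all tumours and 483 in adenocarcinomas, with a median ratio of adjusted to unadjusted log2 differences of 0.737 and 0.922. The p53 or p16 loss of the intact mice goes with the contrast. Against p16 mice alone the counts were 438 and 19, and without mouse m547 the adenocarcinoma count was 412.

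Within Lkb1 loss, tumours with a squamous component (3 mice) and adenocarcinomas (4 mice) differed at 1414 probe sets, 866 higher and 548 lower in squamous tumours. All 3 mice with squamous or mixed tumours were L/-, while 2 of the 4 with adenocarcinomas were L/L, and L/- mice alone gave 650 probe sets. The probe set with the largest increase, again without overlap, rose from 4.63 ± 0.64 (SD, n = 4) in adenocarcinomas to 12.1 ± 0.20 (n = 3) in squamous or mixed tumours, a log2 difference of 7.47 (SE 0.33, limma adjusted p = 0.000145). The probe set with the largest decrease among those without overlap fell from 11.6 ± 1.29 to 7.25 ± 1.36, a log2 difference of -4.35 (SE 0.82, limma adjusted p = 0.0261). In this comparison 41 probe sets rose and 6 fell by more than 8-fold. The Gapdh difference was 0.33 ± 0.16 in squamous or mixed tumours (n = 3) and 1.06 ± 0.98 in adenocarcinomas (n = 4), which an exact permutation test did not separate (p = 0.229). Leaving out mouse m113, m540, m547 or the mixed mouse m452 left 496, 570, 575 and 633 probe sets.

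The 2 control genotypes, p53 loss (5 mice) and p16 loss (2 mice), differed at 0 of 22690 probe sets (limma), with 1500 at an unadjusted p under 0.05. In simulated data of this design 38.8% of probe sets changed by a log2 of 1 were recovered, so real differences can be missed. With an intensity trend and robust prior 1 probe set passed, and without the p16 mouse m91 13 did.

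The first 2 principal components of the mouse arrays held 35.8% and 13% of the variance. Correlations between mouse arrays ran from 0.894 to 0.986, and between arrays of the same mouse from 0.956 to 0.986.

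**Figure D1:**
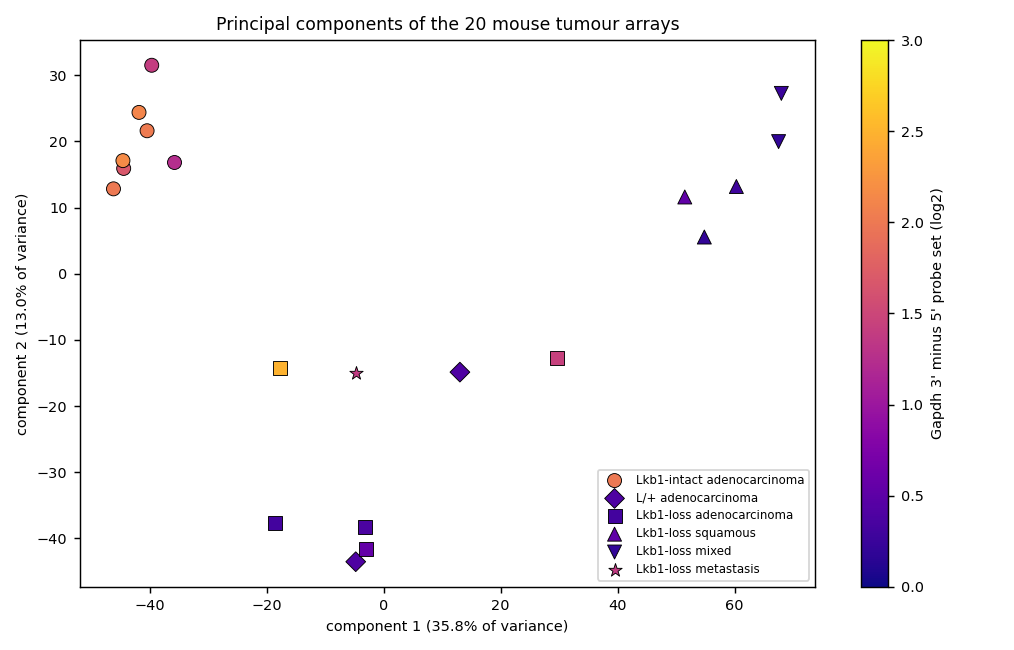
Principal components 1 and 2 (scores, with percent of variance on each axis) of the 20 mouse arrays, each point 1 array, its shape the genotype and histology group and its colour the 3' minus 5' difference of Gapdh in log2 units. Lkb1-intact arrays lie at component 1 scores of -35.8 or below, and squamous and mixed arrays at 51.5 or above.

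On the cell line arrays the median net signal of the sample channel was 388 to 641 on 8 arrays and 113 to 159 on the 4 arrays labelled H2126 LKB1-WT, where 87.3 to 90.7% of probes lay above background against 91.4 to 94.9% on the others. These 4 arrays correlated with the other 8 at 0.162 to 0.220 and with each other at 0.952 to 0.990. A549 arrays correlated with each other at 0.884 to 0.978, and A549 with H2126 parental arrays at 0.485 to 0.586.

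**Figure D2:**
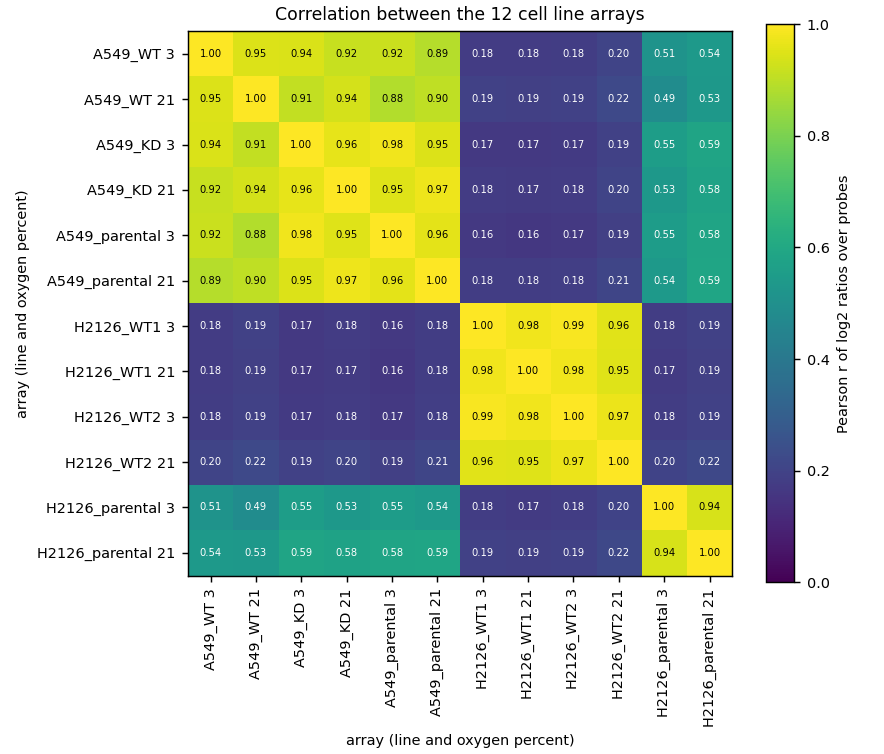
Pearson correlation of log2 ratios over probes (colour, no unit) between the 12 cell line arrays, named on both axes by derivative line and percent oxygen. The 4 arrays labelled H2126 LKB1-WT correlate with the 8 others at 0.162 to 0.220.

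STK11, on chromosome 19, was read first as a check of the labels. All signs take the near-constant channel 1 as the reference, opposite to the label. Its log2 ratio over the reference was 0.09 ± 0.03 (SD, n = 2) in A549 LKB1-WT, -0.07 ± 0.06 in A549 kinase-dead and 0.03 ± 0.09 in A549 parental, so the transcript did not separate these derivatives (limma adjusted p = 1.00 for LKB1-WT against kinase-dead). Whether the probe lies in the introduced sequence is not known, and it therefore checks nothing in A549. In H2126 the ratio was -1.31 ± 0.19 (n = 2) in parental cells and -0.02 ± 0.05 (n = 4) in the libraries labelled LKB1-WT. That difference of 1.29 was 5.22 on the other STK11 probe and turned to -0.69 with median centring in place of loess.

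A549 cells labelled LKB1-WT were compared with cells carrying kinase-dead LKB1, the closest control. The secreted matrix protein SPARC rose by a log2 difference of 4.94 (SE 0.21, adjusted p = 2.97e-06) and COL1A1, a chain of type I collagen, by 3.79 (SE 0.26, adjusted p = 0.000164). The orphan chemokine receptor CMKOR1 rose by 3.86 (adjusted p = 0.107 without the 4 arrays labelled H2126 LKB1-WT), the sialomucin PODXL by 3.53 and DPYSL3 by 3.30. The largest decreases were MTUS1 at -4.53 (SE 0.41, adjusted p = 0.000561), TSC, named in the files as a hypothetical protein of chromosome 12 and not a tuberous sclerosis gene, at -4.27, contactin CNTN1 at -4.23, neuronal pentraxin NPTX1 at -4.11 and the cAMP phosphodiesterase PDE4B at -3.78 (SE 0.16, adjusted p = 2.97e-06). In all 266 of 18018 genes changed, 106 higher and 160 lower (limma, 2 arrays a group), and 169 did without the 4 arrays labelled H2126 LKB1-WT. The count was 456 without background correction, 400 on the series matrix, 503 with every probe tested and 1024 with A549 arrays alone. Leaving out 1 of the 4 A549 arrays gave 85, 88, 94 or 185 genes.

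Among the study genes, NEDD9, a scaffold protein of focal adhesions, fell by 3.18 on the log2 scale (SE 0.48, limma adjusted p = 0.0106) and the surface antigen CD24 fell by 2.89 (SE 0.51, adjusted p = 0.0209). VEGFC, a growth factor for lymphatic vessels, had a difference of -0.95 (SE 0.37, adjusted p = 0.484). Over all genes 2 of these 3 passed, and 3 did adjusted over the list alone (VEGFC 0.0299). Of 4 CD24 probes 3 had differences of -2.89, -2.56 and -2.44 and the dimmest -0.36. The study chose this list on these samples, so its direction is not independent evidence. Without the 4 arrays labelled H2126 LKB1-WT the adjusted p of NEDD9 was 0.0901 and that of CD24 was 0.143. The log2 differences, taken from A549 arrays only, stayed the same, and the degrees of freedom went from 9.99 to 5.72. CDKN2A and KRAS2 had differences of -0.18 and 0.23, neither past the threshold.

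**Figure D3:**
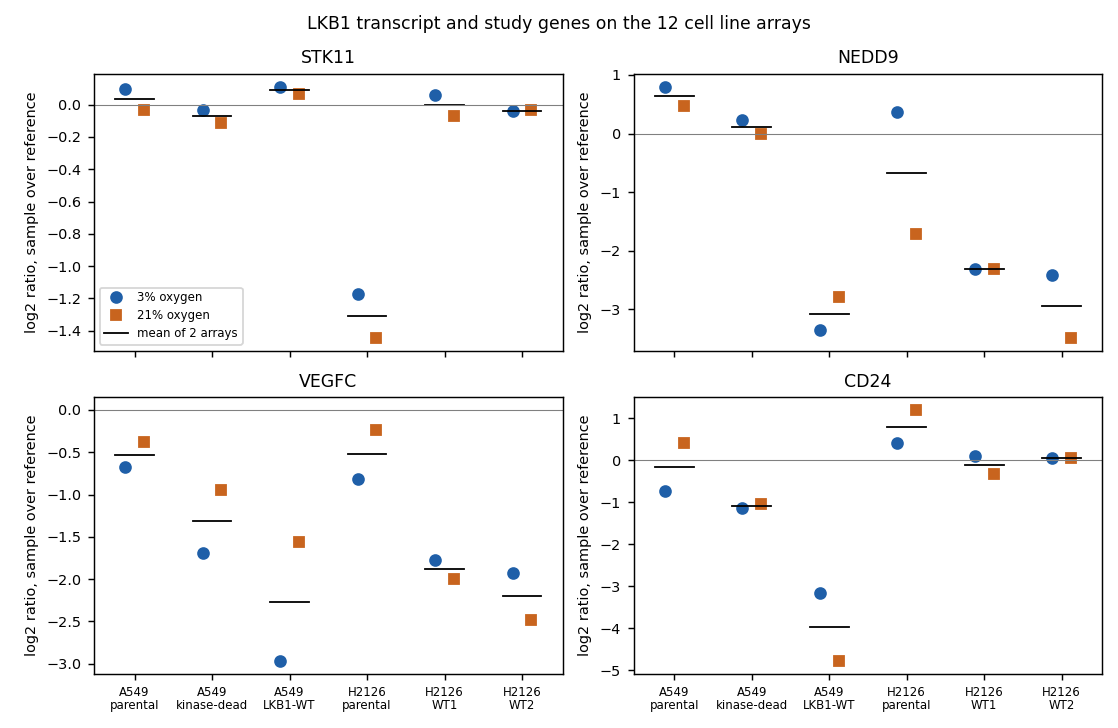
Log2 ratio of sample over reference (vertical axis) of STK11, NEDD9, VEGFC and CD24 in the 6 derivative lines (horizontal axis), with points for the arrays at 3% and 21% oxygen and lines for their mean. In A549 the NEDD9 mean is -3.07 with LKB1-WT, 0.11 with kinase-dead LKB1 and 0.64 in parental cells.

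CREB and CRTC targets, the genes switched on by cAMP signalling, fell as a list in A549 LKB1-WT (camera adjusted p = 1.31e-09, and adjusted p = 0.0347 with an estimated correlation). Of 21 measured, 8 fell, 1 rose and 12 did not pass, and adjusted over the list alone 10 fell and 2 rose, with a median log2 difference of -0.29. The nuclear receptor NR4A1 fell by 2.69 (SE 0.25, adjusted p = 0.000695), and the differences of C6orf176 and the phosphodiesterase PDE4D were -2.99 and -2.33. The growth factor AREG, NR4A3, PDE10A and the phosphatase DUSP1 fell, with differences of -1.96, -1.62, -1.53 and -1.16, while the hormone STC1 rose by 1.01. Without the 4 arrays labelled H2126 LKB1-WT, 5 fell and 1 rose. There the list had camera adjusted p = 4.72e-06 at the preset correlation and 0.148 with an estimated one. That estimate, -0.007, lay below the preset 0.01, so correlation between genes does not account for the higher p.

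Genes of EMT and invasion had a median difference of 0.42, with 18 of 20 above 0. Of these 1 rose (limma; 0 without the 4 arrays labelled H2126 LKB1-WT), and 8 rose adjusted over the list alone (4 without those arrays). The camera call (adjusted p = 1.36e-07) was lost at adjusted p = 0.116 with an estimated correlation. Fibroblast and matrix genes had a median of 0.36, with 21 of 22 above 0. SPARC and COL1A1 rose, 4 rose adjusted over the list alone (2 without those arrays), and camera's adjusted p of 9.49e-09 became 0.371 with an estimated correlation. Gut-like and mucinous genes fell at 3 of 22, namely AGR2 (-3.0), the claudin CLDN2 (-1.67) and the mucin MUC5AC (-1.49), while the list itself did not pass (camera adjusted p = 0.104). Adjusted over the list alone 3 fell and 1 rose. Without the 4 arrays labelled H2126 LKB1-WT the adjusted p of AGR2, CLDN2 and MUC5AC was 0.0685, 0.144 and 0.0605, and these 3 passed adjusted over the list alone.

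Sterol and fatty acid synthesis had a median of 0.27, with 21 of 26 above 0 and 0 past the threshold, also adjusted over the list alone (1 without the 4 arrays labelled H2126 LKB1-WT). The fatty acid elongase ELOVL6 had a difference of 0.40 (SE 0.14, limma adjusted p = 0.367). NRF2 targets, the oxidative stress genes, had a median of -0.18 and 0 past, and 2 fell adjusted over the list alone (0 without those arrays). AKR1C3 had -1.47 (adjusted p = 0.0740) and AKR1C1 had -1.85 (adjusted p = 0.106), and with median centring these adjusted p were 0.00375 and 0.0022. The AKR1C1 probe carries the gene name of member C2 of the same family, so its gene is uncertain. The camera calls of both lists (adjusted p = 0.00324 and 0.000868) were lost at adjusted p = 0.559 with an estimated correlation. ATF4 targets fell at 2 of 23, the amino acid carriers SLC7A5 (-1.03) and SLC3A2 (-0.81; adjusted p = 0.155 with median centring), and at 5 adjusted over the list alone (3 without those arrays). Their camera call (adjusted p = 0.0131) was lost at adjusted p = 0.655 with an estimated correlation. Without the 4 arrays labelled H2126 LKB1-WT it was lost at the preset correlation too (adjusted p = 0.0884), and SLC7A5 had adjusted p = 0.0801 and SLC3A2 0.0491.

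The other 6 lists were not called by camera. Hypoxia genes held DDIT4, which fell by 1.76 (SE 0.18), and the hexokinase HK2, which rose by 1.17, around a median of 0.00 (camera adjusted p = 0.717). Squamous and basal genes held the keratin KRT15, which rose by 0.90, and E-cadherin CDH1, which fell by 1.86, around a median of 0.08 (camera adjusted p = 0.726). Without the 4 arrays labelled H2126 LKB1-WT, DDIT4 passed (adjusted p = 0.0178), and HK2 (0.159), KRT15 (0.0528) and CDH1 (0.183) did not. Alveolar type 2 genes had a median of 0.00, proliferation genes -0.04, p53 targets 0.05 and interferon genes 0.09, with 0 past in each, and 1 interferon gene higher and 1 lower adjusted over the list alone (0 and 0 without those arrays). The mean of the squamous list was -0.02 and that of the alveolar list -0.02, and camera put the alveolar and hypoxia lists down, against their medians. With median centring the gut-like, hypoxia and interferon medians turned to 0.02, -0.12 and -0.04, and without background correction the alveolar median turned to -0.02.

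**Figure D4:**
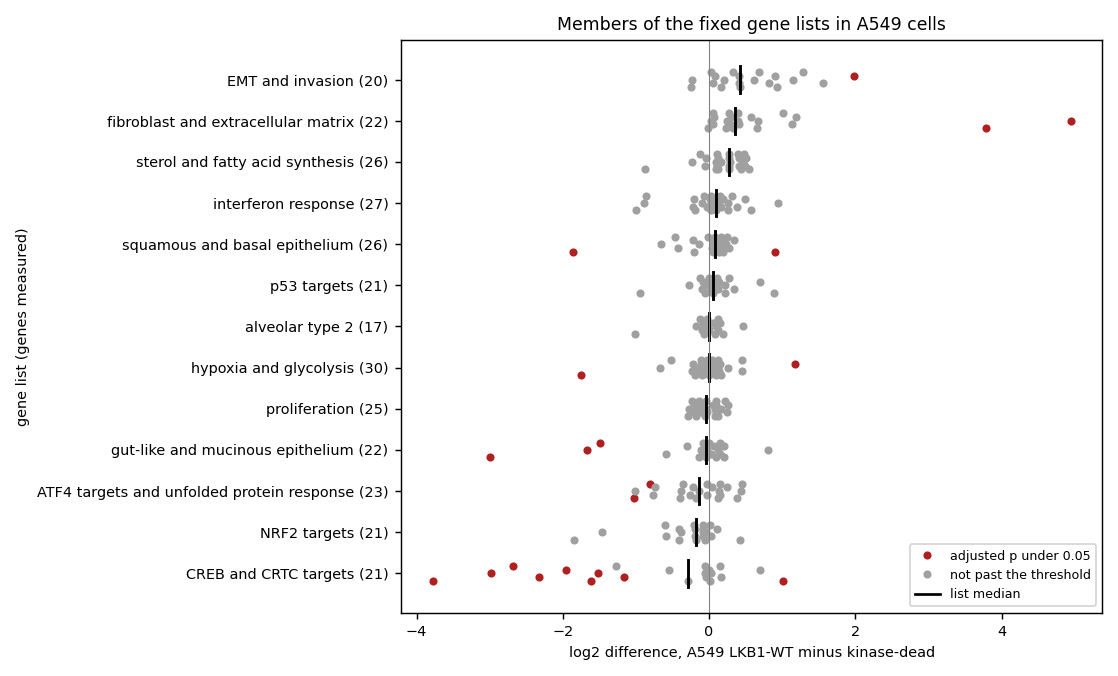
Log2 difference between A549 LKB1-WT and kinase-dead cells (horizontal axis) of the measured members of 13 fixed gene lists (vertical axis), each point 1 gene, red where the limma adjusted p is under 0.05, with a black line at the list median. CREB and CRTC targets have the lowest median, -0.29, and EMT and invasion the highest, 0.42; the alveolar, gut-like, hypoxia and interferon medians change sign with another scaling.

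The kinase-dead construct alone, against A549 parental cells, shifted 3 genes down on the log2 scale (limma): the protease inhibitor SPINK6 by -2.49 (SE 0.15, adjusted p = 0.000191), the DNA binding inhibitor ID4 by -2.48 (SE 0.28, adjusted p = 0.0299) and the neurofilament chain NEFL by -1.61 (SE 0.14, adjusted p = 0.00410). Of 18018 genes 435 had an unadjusted p under 0.05, a smaller share than chance alone gives. In simulated data of this design 52.2% of genes changed by a log2 of 1 were recovered, and 1.49% at 0.5. The low count therefore does not show that the construct changes little. ID4 had adjusted p = 0.238 without the 4 arrays labelled H2126 LKB1-WT, and NEFL 0.0777 without background correction, where 3 genes were higher and 7 lower, against 4 and 13 on the scanner's processed log ratio and 11 and 16 with median centring. NEDD9, VEGFC and CD24 had differences of -0.53, -0.79 and -0.93, with 0 of 3 past over all genes or adjusted over the list alone. CREB and CRTC targets had a median of -0.24, led by PPARGC1A at -0.72 and C6orf176 at -1.25, 0 past and 2 lower adjusted over the list alone, and camera's adjusted p of 3.13e-06 became 0.0905 with an estimated correlation. Hypoxia genes had a median of -0.06, with DDIT4 at -0.78 and EGLN3 at -0.69, and camera's adjusted p of 0.0162 became 0.141 with an estimated correlation. Proliferation (0.05), sterol synthesis (-0.06), ATF4 targets (-0.15) and fibroblast genes (-0.15) were called by camera and lost at adjusted p = 0.610 with an estimated correlation. The medians of the other 7 lists lay between -0.09 and -0.02, none called, and that of interferon genes turned to 0.02 with median centring.

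Against parental A549 cells, LKB1-WT cells changed at 526 genes, 217 higher and 309 lower (limma). This comparison was not among those fixed before the data were examined. SPARC rose by 4.86 (SE 0.21, adjusted p = 2.82e-06), PODXL by 4.85, DPYSL3 by 4.72, FLRT2 by 4.0 and COL1A1 by 3.96. The adhesion molecule CEACAM6 fell by 5.09 (SE 0.31, adjusted p = 2.99e-05), and COL4A6, NNMT, CTEN and TSC had differences of -4.96, -4.96, -4.94 and -4.83. NEDD9, CD24 and VEGFC fell, with differences of -3.71, -3.82 and -1.73 (VEGFC adjusted p = 0.0355), so that 3 of 3 study genes passed over all genes and adjusted over the list alone. The study chose them on these samples, so this is not independent evidence. Parental cells do not control for the construct. VEGFC had -0.79 in kinase-dead against parental cells, and -0.95 in LKB1-WT against kinase-dead cells (limma adjusted p = 0.484). The comparison with parental cells was not fitted without the arrays labelled H2126 LKB1-WT.

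The libraries labelled H2126 LKB1-WT differed from H2126 parental cells at 14182 of 18018 genes, 8669 higher and 5513 lower (limma, 4 against 2 arrays). The gap junction protein GJA1 was higher by 10.60 (SE 0.37, adjusted p = 7.08e-09), the forkhead factor FOXG1B by 10.08, CUGBP2 by 7.81, the collagen COL8A1 by 7.59 and the kinase SGK by 7.32. Carboxypeptidase CPE had a difference of -7.26 (SE 0.35, adjusted p = 2.71e-08), above background on 2 of 4 arrays, and ALDH1A3, PPT1, PSCA and MDH2 had -7.08, -7.06, -6.39 and -6.12. NEDD9 fell by 1.96 (adjusted p = 0.00137) and VEGFC by 1.52 (adjusted p = 0.00140), while CD24 had -0.83 (adjusted p = 0.106), so 2 of 3 passed over all genes and adjusted over the list alone. The log2 ratio of NEDD9 to the reference was 0.36 at 3% and -1.71 at 21% oxygen on the 2 parental arrays, and with median centring the NEDD9 and VEGFC differences were -4.17 and -3.81. Probes disagreed in size: the other NEDD9 probe had -0.73, the other VEGFC probe -0.31 (limma adjusted p = 0.359 over all probes), and the other CD24 probes -3.07, -2.33 and 0.01. CDKN2A and KRAS2 were higher by 2.75 and 2.25, and with median centring neither passed while CD24 did. The median of all genes was 0.31, and -0.07 with median centring, where 7468 genes were higher and 7969 lower.

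For the lists called by camera the median is given relative to that of all genes, and single genes as plain log2 differences. Fibroblast genes stood 2.47 above the median of all genes, with 21 of 22 higher, such as COL5A1 (3.49), PDGFRA (3.46) and COL5A2 (3.44), and 0 lower. EMT genes stood 2.13 above it, with 15 of 20 higher, such as SNAI2 (3.58) and FOXC2 (3.11), and 2 lower. NRF2 targets stood at -2.02 with 15 of 21 lower, such as FTL (-5.21) and NQO1 (-4.44), and 3 higher. GCLM was not well above background in the libraries labelled LKB1-WT, and no fold is given for it. ATF4 targets stood at -1.56 with 14 of 23 lower, such as HSPA5 (-4.51), ATF4 (-4.21) and HERPUD1 (-3.44), and 5 higher, and proliferation genes at -1.33 with 16 of 25 lower, such as TYMS (-5.42), TK1 (-4.95) and MCM7 (-3.54), and 7 higher. Of all genes 48.1% were higher and 30.6% lower. Counts adjusted over the list alone were the same for these lists. Camera called these 5 lists, and all were lost with an estimated correlation (adjusted p = 0.473, and 0.545 for ATF4 targets). The other 8 lists were not called, and their medians are plain log2 differences, not relative to that of all genes. They were 1.58 for CREB and CRTC targets, 0.89 for gut-like, 0.86 for interferon, 0.80 for alveolar type 2, 0.79 for squamous, 0.19 for p53, -0.26 for sterol and -0.55 for hypoxia genes. The squamous and p53 medians turned to -0.14 and -1.03 with median centring.

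Across both lines, with 3 derivative lines labelled LKB1-WT and 3 without active LKB1, 0 genes passed (limma) and 1553 had an unadjusted p under 0.05. In simulated data of this design 0% of genes changed by a log2 of 1 or 2 were recovered. The count of 0 therefore does not show that no gene changed. Of the 3 lines labelled LKB1-WT, 2 are the H2126 lines whose arrays stood apart. INSL4 (-4.58, SE 0.33), AVPI1 (-2.34, SE 0.17) and LFNG (2.90, SE 0.23) had the smallest p, each with adjusted p = 0.278. NEDD9, VEGFC and CD24 had differences of -2.70, -1.43 and -2.09, and 0 of 3 passed over all genes against 3 adjusted over the list alone. That list was chosen on these samples, so the latter count is not independent evidence. Fibroblast genes lay above 0 at 22 of 22, with a median of 1.57 and 6 higher adjusted over the list alone, among them SPARC (3.99) and COL1A1 (2.88). EMT genes had a median of 1.33 and 3 higher adjusted over the list alone, with CDH2 at 2.13. The fibroblast and EMT medians were 0.36 and 0.42 in A549 LKB1-WT against kinase-dead. In the libraries labelled H2126 LKB1-WT against parental they were 2.78 and 2.44. NRF2 targets had a median of -0.72 (SLC7A11 -1.61, PGD -0.62), ATF4 targets -0.52 (ATF3 -1.61, SLC3A2 -1.36) and proliferation genes -0.57 (RRM2 -1.72, TOP2A -0.97). Camera called these 5 lists and none held with an estimated correlation (adjusted p = 0.426, 0.392, 0.385, 0.385 and 0.460 in this order). The medians of the other lists lay between -0.26 (hypoxia) and 0.51 (squamous), none called. CREB and CRTC targets had a median of 0.49 and a mean of 0.12 although camera put them down, with 2 lower adjusted over the list alone. The median of all genes was 0.16, and -0.07 with median centring. The squamous, p53 and CREB medians turned to -0.17, -0.54 and -0.43 with median centring. With A549_WT left out 13383 genes passed, with H2126 parental left out 297, and with the derivative line as a random block 8.

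LKB1-WT minus parental differed between the lines at 12184 genes, 4796 higher and 7388 lower in A549 (limma). The median of all genes was -0.31 there, and 0.04 with median centring, where 7099 genes were higher and 5787 lower. The H2126 part rests on the arrays labelled H2126 LKB1-WT, which stood apart from all others. The count therefore cannot be read as a difference in LKB1 effect alone. Of 106 genes that rose in A549 LKB1-WT against kinase-dead, 70 were higher and 12 lower in the libraries labelled H2126 LKB1-WT, where 48.1% of all genes were higher. Of 160 that fell, 83 were lower and 54 higher, against 30.6% of all genes lower. Across genes, which are not independent replicates, LKB1-WT minus parental in A549 and in H2126 correlated at r = 0.118. CREB and CRTC targets were lower in A549 at 17 of 21, also adjusted over the list alone, with a median of -2.21, and the camera call (adjusted p = 0.00155) was lost at adjusted p = 0.284 with an estimated correlation. Fibroblast (median -2.47, 16 lower, 17 adjusted over the list alone), NRF2 (1.70), ATF4 (0.98) and proliferation genes (0.96) were called and lost at adjusted p = 0.63 with an estimated correlation. The 8 other lists were not called, with medians from -1.29 (EMT) to 0.74 (hypoxia), and the p53 and interferon medians, -0.52 and -0.70, turned to 1.03 and 0.20 with median centring. Of the study genes 2 of 3 differed, over all genes and adjusted over the list alone: NEDD9 at -1.76, which turned to 0.16 with median centring, 0.09 on the processed log ratio and 0.10 on the series matrix, and CD24 at -2.99 on 1 probe. The other 3 CD24 probes had LKB1-WT minus parental differences of -3.46, -3.25 and -0.74 in A549 and -3.07, -2.33 and 0.01 in H2126.

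At 3% against 21% oxygen, ACAT2, an enzyme of cholesterol metabolism, was the gene past the threshold over 6 pairs, higher by 0.81 (SE 0.08, limma adjusted p = 0.0347) and higher in 6 of 6 pairs, while 2849 genes had an unadjusted p under 0.05. Its adjusted p was 0.0554 on the scanner's processed log ratio and 0.0574 on the series matrix. Hypoxia and glycolysis genes rose as a list, with 24 of 30 above 0, a median of 0.20 and 10 higher adjusted over the list alone (camera adjusted p = 1.07e-05, and adjusted p = 0.0369 with an estimated correlation). The latter was lost at adjusted p = 0.441 without the 4 arrays labelled H2126 LKB1-WT, where 7 rose and 3 fell adjusted over the list alone. The mitochondrial kinase PDK1 had 0.81 (adjusted p = 0.0695) and the oxygen sensor EGLN3 0.54 (adjusted p = 0.104). Sterol synthesis genes lay above 0 at 24 of 26, with a median of 0.35 and 18 higher adjusted over the list alone, such as IDI1 (0.81) and MVD (0.69), and camera's adjusted p of 2.66e-12 became 0.203 with an estimated correlation. Proliferation genes had a median of 0.10 (KIF11 0.47, MKI67 0.41), 2 higher adjusted over the list alone and camera adjusted p = 0.00617, lost at 0.607 with an estimated correlation. NRF2 targets had a median of 0.21 (GSR 0.34, TXNRD1 0.29), camera adjusted p = 0.0156, lost at adjusted p = 0.708 with an estimated correlation. The other 9 lists were not called, with medians between -0.14 (ATF4 targets) and 0.06 (fibroblast genes). The squamous list had a median of -0.04 and a mean of 0.05, and p53 targets a median of -0.02 although camera put them up. Without background correction the CREB, interferon and fibroblast medians turned to -0.03, -0.02 and -0.01. NEDD9, VEGFC and CD24 had 0.53, -0.38 and 0.00, with 0 of 3 past over all genes or adjusted over the list alone.

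Without the 4 arrays labelled H2126 LKB1-WT, 452 genes passed over 4 pairs, 264 higher and 188 lower at 3% oxygen (limma). The untranslated RNA H19 rose by 1.90 (SE 0.09, adjusted p = 0.0253), troponin TNNC1 by 1.62, SLC2A14 by 1.35, SAA1 by 1.32 and NDRG1 by 1.30 (SE 0.14, adjusted p = 0.0290). For the SLC2A14 probe the files give that symbol beside the name of member 3 of the same glucose transporter family, so its gene is uncertain. PHLDB2, P4HA3, PEX6, PVRL2 and GGCX fell, with differences of -1.62, -1.51, -1.36, -1.23 and -1.21. Sterol synthesis rose at 6 of 26 genes, among them IDI1 by 1.02 (SE 0.13, adjusted p = 0.0324) and INSIG1 by 1.01. Of 30 hypoxia genes NDRG1 and PDK1 (0.95) rose and P4HA1 fell by 0.64, and adjusted over the list alone 7 rose and 3 fell. Among p53 targets TP53INP1 rose by 0.55, and SESN2, TNFRSF6 and PMAIP1 fell, with differences of -0.69, -0.57 and -0.45, while the list was not called (camera adjusted p = 0.638). MKI67 (0.55) and KIF11 (0.50) of the proliferation list rose, and DNAJB9 of the ATF4 list fell by 0.49. Camera called both lists (adjusted p = 0.0186 and 0.00379), and both were lost at adjusted p = 0.756 with an estimated correlation. Sterol and hypoxia genes were called by camera too (adjusted p = 1.16e-10 and 0.00465), and were lost at 0.533 and 0.441 with an estimated correlation. For hypoxia genes that estimate was -0.011, below the preset 0.01, so correlation between genes does not account for the loss. The 4 pairs cannot give the test across splits a share under 0.05.

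**Figure D5:**
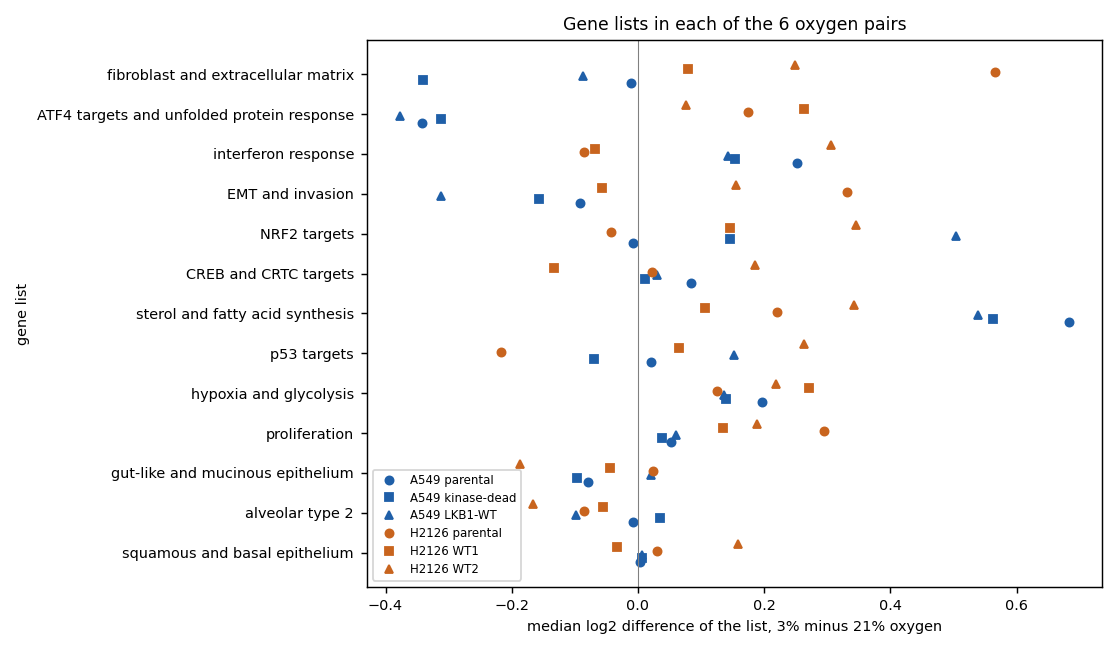
Median log2 difference between 3% and 21% oxygen (horizontal axis) of the members of 13 fixed gene lists (vertical axis) in each of the 6 derivative lines, each point 1 oxygen pair, blue for A549 and orange for H2126. Sterol synthesis medians run from 0.54 to 0.68 in A549 and from 0.11 to 0.34 in H2126, and hypoxia medians lie above 0 in 6 of 6 pairs.

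The oxygen effect differed between A549 and H2126 at 54 genes, 18 higher and 36 lower in A549 (limma), against 102 and 72 without background correction and 27 and 24 on the scanner's processed log ratio. Of the 3 H2126 pairs 2 are labelled LKB1-WT, and without these 4 arrays 1301 genes differed, 488 higher and 813 lower. ATF4 targets responded lower in A549 as a list, with a median of -0.52, 3 of 23 lower and 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.43e-08, and adjusted p = 0.0329 with an estimated correlation). The serine enzyme PHGDH stood at -1.29 (SE 0.19, adjusted p = 0.0390), the asparagine synthetase ASNS at -1.22 and the stress factor XBP1 at -1.04. HMGCS1, of cholesterol synthesis, was higher in A549 by 1.92 (SE 0.16, adjusted p = 0.00745). Sterol genes had a median of 0.26 and 7 higher adjusted over the list alone, and fibroblast genes -0.57 with COL5A1 at -1.41 and 9 lower adjusted over the list alone. EMT genes had a median of -0.16, with 6 lower adjusted over the list alone, and squamous genes 0.22. Of the alveolar list the complement gene C5 was lower by a log2 difference of -2.02 (SE 0.24, adjusted p = 0.0251). Camera called these 4 lists, lost with an estimated correlation at adjusted p = 0.135 for sterol genes and 0.168 for the others. Interferon (0.14) and proliferation genes (-0.12) were called and lost at adjusted p = 0.464 with an estimated correlation. The other 6 medians lay between -0.05 (hypoxia) and 0.19 (alveolar type 2), none called. Means of the alveolar and gut-like lists were -0.04 and -0.03 against medians of 0.19 and 0.09, the CREB list had -0.01 and a mean of 0.04, and all 3 with the hypoxia list changed sign without background correction (-0.03, -0.03, 0.11 and 0.08). Without A549 kinase-dead, H2126 WT1 or H2126 WT2, 0 genes passed, without A549 parental 2 and without A549_WT 6, while 151 did without H2126 parental.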

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

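The tests of probe agreement within a gene and of the p53 or p16 loss were chosen after their result was seen, as were the 16 settings of the probe position test, set after a first single run.

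The 4 arrays labelled H2126 LKB1-WT stood apart from the 8 others, and human RNA that differs only in transcript levels would move 2 probes of a gene alike. Over 8390 genes, their differences from parental correlated at 0.459 (95% bootstrap interval 0.438 to 0.480), against 0.864 (0.850 to 0.877) for H2126 parental against A549 parental, which argues against other transcript levels as the whole cause. RNA degraded from the 5' end, and RNA of another organism on human probes, both remain open. The median of the downstream minus the upstream probe was -0.1496 (95% interval -0.269 to -0.0298), the outcome named beforehand as against degradation and for another organism. The interval lay below 0 in only 10 of 16 settings. On other contrasts it did so in 9 of 48 cases, all of A549 LKB1-WT against parental, with medians of -0.01 to -0.05. It lay above 0, as degradation from the 5' end needs, in 0 of 16 settings, and a verdict was kept only where every setting gave it, a rule made after the first run. The files do not say what the number ending a probe name means, on which this test rests and which keeps both open.

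Mouse m459, an Lkb1-loss adenocarcinoma, lay far from the other Lkb1-loss mice in the 3' to 5' difference of Gapdh, at 2.487 against 0.2256 to 0.9052, and of actin, at 2.90 against 0.755 to 1.463. The Gapdh difference as a covariate left a median ratio of adjusted to unadjusted log2 differences of 0.9223 over 1337 adenocarcinoma probe sets (0.898 to 0.980 with each mouse left out). That is the outcome named beforehand as against 3' bias. It cannot decide the question, since these probe sets were picked by the fit without the covariate, which can favour a ratio near 1. Mouse m459, with a Gapdh difference as high as in intact mice, lay at 0.478 between the intact (0) and Lkb1-loss (1) adenocarcinoma means on an axis made without it. Their median size went from 0.853 to 0.778 and the median SE from 0.183 to 0.200, and 483 probe sets passed; over all tumours the ratio was 0.737, the SE went from 0.145 to 0.180 and 363 passed. Calls ended with smaller differences and a larger SE, and without m459 the adjusted SE was 0.353. Loss of p53 or p16 in the control mice stays open, since the L/+ tumours, of 1 mouse, lay at 0.8887 between the intact (0) and Lkb1-loss (1) adenocarcinoma means. Both L/+ tumours had a Gapdh difference of 0.39, against 1.24 to 2.16 in the intact mice, so RNA quality goes with that position.

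On the axis from intact (0) to Lkb1-loss (1) adenocarcinomas the metastasis lay at 0.81195 and the L/+ tumours, outside both groups, at 0.9726 and 0.80478, against -0.120 to 0.0799 for the intact arrays, which set the 0. Without its own mouse in the axis the metastasis lay at 0.843, the intact arrays at -0.0700 to 0.272 and the Lkb1-loss mouse m459 at 0.478. The probe set with the largest rise in squamous tumours stood at 7.097 in the intact mouse m500, against 4.146 to 5.069 in the other intact mice. The oxygen difference of DNAJB9, a chaperone, was 0.7597 in H2126_WT2 and -0.6329 to -0.2948 in the other 5 pairs. Of 53 groups of values tested 4 held a far value, and chance gives about 1 in 20.

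LKB1-WT minus parental differed between A549 and H2126 at 12184 genes, and the oxygen effect at 54 (limma). The LKB1 difference of STK11 was -1.232 (limma adjusted p = 0.000151), of NEDD9 -1.757 (adjusted p = 0.0310) and of CD24 -2.987 (adjusted p = 0.00258). The NEDD9 value turned to 0.16 with median centring, 0.09 on the processed log ratio and 0.10 on the series matrix, and the H2126 part of the STK11 value reversed to -0.69 with median centring. The CD24 value rests on 1 probe: LKB1-WT minus parental was -3.46, -3.25 and -0.74 on the other 3 in A549, against -3.07, -2.33 and 0.01 in H2126. That of VEGFC was -0.22 (adjusted p = 0.717), not past the threshold. All these rest on the 4 arrays labelled H2126 LKB1-WT.

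Other splits of the samples were fitted for each comparison of groups; where 100 were drawn, the draw holds the highest split of 2 earlier draws beside randomly drawn ones. For all primary tumours 1 of 100 splits, the real one with 5201 probe sets, gave as many, and the highest other gave 225. For adenocarcinomas 1 of 100 did, with 1337 against 272. For squamous tumours 1 of 35 did, with 1414 against 0. Chance alone is thus an unlikely source of these 3 counts, but the number of splits cannot exclude it. The splits also do not tell Lkb1 loss from the p53 or p16 loss of the intact mice or from the Gapdh difference. For oxygen 1 of 32 did, with 1 gene against 0, which rests on ACAT2 alone and excludes nothing, since 0 genes passed on the processed log ratio, the series matrix or every probe. The 9 splits across both cell lines (0 genes, highest other 0), the 8 of oxygen without the 4 arrays (452, 0) and the 10 of the oxygen difference (54, 0) are too few for a share under 0.05. Across both cell lines any split also reaches the real count of 0, so that test could not separate it.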

How the results depend on the processing

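The Gapdh covariate, the fits without the 4 arrays labelled H2126 LKB1-WT or with A549 alone, and single arrays left out were chosen after the data were seen. Apart from left-out replicates 50 counts stayed within 1.5 times and 45 moved, and with replicates left out 40 stayed and 31 moved; the cause was not tested. For all tumours 5201 became 2934 (p53 controls), 438 (p16 controls), 2689 (L/+ mouse with the intact) and 363 (Gapdh), and 3305 to 6479 with a mouse left out. For adenocarcinomas 1337 became 851, 19, 105 and 483 in the same order, 581 (L/L only) and 220 (L/- only), and 412 to 2042. For squamous tumours 1414 became 2261 (mouse as a random block), 633 (no mixed mouse) and 650 (L/- only), and 496 to 1341. For p53 against p16 the range was 0 to 13, and 1 with a trend and robust prior.

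For A549 LKB1-WT against kinase-dead 266 became 456 (no background correction), 400 (series matrix), 503 (every probe), 169 (without the 4 arrays) and 1024 (A549 alone), and 85 to 185. For kinase-dead against parental 3 became 10 (no background correction), 17 (processed log ratio or matrix), 27 (median centring) and 44 (A549 alone), and 1 to 7. For H2126 every probe gave 28340 and left-out arrays 12485 to 14744; its STK11 difference reversed to -0.69 with median centring. Across both lines 0 became 7302 (12 arrays as if independent) and 2063 (A549 alone), and 0 to 13383. For oxygen 1 became 0 (processed log ratio, matrix, every probe), 31 (median centring), 452 (without the 4 arrays) and 2456 (A549 alone), and 0 to 50. The LKB1 difference gave 23375 with every probe, the oxygen difference 174 (no background correction), 1301 (without the 4 arrays) and 0 to 151. Camera's called lists went, with an estimated correlation, from 5 to 0 across both lines, 6 to 1 in A549 LKB1-WT against kinase-dead, 6 to 0 in kinase-dead, 5 to 0 in H2126, 4 to 1 for oxygen, 5 to 0 for the LKB1 and 7 to 1 for the oxygen difference.

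The pairing by derivative line changed counts: oxygen gave 0 genes with no replicate block, and both lines gave 8 with derivative line as a random block. Not run were a slide or scan block, the random mouse block for adenocarcinomas and for p53 against p16, collapse of probe sets to genes, and the mouse lists and Lkb1-loss genes in cell lines. The low signal of the 4 arrays limits what H2126 can show.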

Other observations

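The values here were picked after they were seen. On the axis from Lkb1-loss adenocarcinomas (0) to squamous or mixed tumours (1), the L/+ tumours lay at 0.05 and 0.34 and the metastasis at 0.10. With their own mouse left out of the axis, the mixed tumours lay at 0.84 and 0.90.

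The oxygen response of 1 A549 derivative correlated with that of another at 0.521 to 0.689 across genes, which are not independent replicates, and all other pairs of derivative lines at 0.277 or below.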
